A study of Caenorhabditis elegans with 9 samples.

How the data were processed

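RNA recovered by anti-GFP immunoprecipitation from Caenorhabditis elegans dauer larvae was measured by sequencing in 9 libraries. Per the labels' protocols, animals were grown at 25 °C and collected at 96 hours, on day 2 of dauer, then fixed with formaldehyde, lysed by sonication and precipitated overnight. RNA was extracted with Trizol directly from the beads, selected for polyadenylated molecules and sequenced as paired ends. Because fixation was followed by whole-transcript extraction, the values measure transcripts recovered with the tagged protein and do not map binding sites. No input RNA was analysed here, so a level in an immunoprecipitate holds both the abundance of a transcript and its recovery.

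Per the submitters' processing notes, Trimmomatic 0.35, STAR 2.7.1a, RSEM and DESeq2 1.30.1 were used with the genome build WBcel235. Their settings are not given in the sources used here. The authors deposited FPKM values, fragments scaled by transcript length and library size, for the 7 libraries made with the intestinal promoter. A second deposited table held a signal per gene and library for the 6 HZL-1 libraries of that set, which were gene reads divided by 1 factor per library. That table also held the authors' log2 fold changes of daf-2 over aak(0), 1 of them per gene from a fitted model and 1 called unshrunken, with standard errors. It listed p-values and adjusted p-values of the authors for the same comparison, and the fitted model is not given in the sources used here. For the 2 libraries made with the endogenous promoter the authors deposited raw counts of reads per gene. Whether those counts used strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be separated.

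In the deposited normalized table every value was a whole multiple of the smallest value of its library, within a tolerance of 0.01 (100% of values in each of the 6 libraries). The whole reads were recovered in this way. Gene reads totalled 7151604, 15881823 and 16749641 in the aak(0) libraries 1 to 3, and 12923984, 17397251 and 11723516 in the daf-2 libraries 1 to 3. The counts table held 24035823 gene reads for aak(0) and 58132094 for daf-2. Entries that name no gene took 62.14% of all reads of that table in aak(0) and 29.63% in daf-2, and they were kept out of library sizes. The depth of the GFP library is unknown. A floor of 3 reads corresponds to between 0.172 and 0.419 CPM (reads scaled to the library's gene reads) in the HZL-1 libraries with the intestinal promoter, and to 0.125 and 0.0516 CPM in the endogenous pair. Such floors and all intervals on counts cover counting error only, since reads without molecular identifiers are not independent molecules.

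Groups were taken from the labels: 3 libraries of HZL-1 under the intestinal promoter in aak(0), 3 in daf-2, 1 of GFP alone in aak(0), and 1 of HZL-1 under its endogenous promoter in each genotype. Nothing in the labels says whether libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Gene symbols were those of the deposited tables for 46904 genes, of which 1117 sequence names and 11 names turned into dates by a spreadsheet were replaced through a gene table of NCBI RefSeq.

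The tests, the 29 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. limma 3.58.1 in R 4.3.3 was fitted with a mean-variance trend to log2(FPKM + 1) of all 7 libraries, with 1 mean per group and 4 residual degrees of freedom. Genes with a mean of at least 1 FPKM over the 7 libraries entered (9649 genes), and a Benjamini-Hochberg adjusted p under 0.05 was the threshold. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The contrasts with GFP assume that the single GFP library varies like the replicated groups. Gene lists were tested with camera at a preset correlation of 0.01, then with an estimated correlation, and with fry, all from limma. Symbol-prefix families with at least 10 tested members were tested likewise. The recovered reads of the 6 HZL-1 libraries were also tested with the quasi-likelihood test of edgeR 4.0.16 and with DESeq2 1.42.0.

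For the endogenous pair the plan had assumed FPKM, and the table held counts. Counts were therefore turned into CPM, with a pseudocount of 1 on the log2 scale and a minimum mean of 1 CPM. With 1 library per genotype no p-value was computed across genes. Ratios carry exact 95% binomial intervals, a count of 0 was replaced by 3 reads for a lower bound, and list medians were placed among 10000 random lists of the same size matched on expression. The named genes were hzl-1, aak-1, aak-2 and nhx-2, then up to 10 in each direction past the threshold with at least 10 FPKM in the higher group and no overlap of libraries. Genes without a symbol were counted and not named. List members named were the most abundant where none passed. For the endogenous pair the 10 largest differences in each direction among genes with a mean of at least 10 CPM were named.

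On simulated reads drawn from the means, dispersions and depths of the real libraries (6927 genes on average for limma, 6462 for edgeR, 3 simulations), limma recovered 1.7% of genes changed 4-fold, 7.7% at 16-fold and 40.3% at 256-fold in the comparison of genotypes. The edgeR test recovered 2.5%, 21.1% and 85.5%. Of the unchanged genes limma called 8 of 20238 and edgeR 4 of 18893. Each gene was drawn on its own, without the zeros that many genes share in some real libraries. These shares may therefore not hold for the real data. Alternatives covered the pseudocount, the filter, 3 other scalings, the variance model, each replicate left out, the replicate number as a block and the tests on reads. Figures were drawn with matplotlib 3.10.9.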

Results

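HZL-1 tagged with GFP was precipitated from dauer larvae, the arrested and stress-resistant larval stage, to ask which transcripts it recovers and whether this depends on AMP-activated protein kinase (AMPK), the cellular energy sensor. All animals carried a mutation in daf-2, the insulin/IGF receptor gene, which drives dauer entry at 25 °C, and those called aak(0) also lacked aak-1 and aak-2, the genes of both catalytic AMPK subunits. Per the labels the hzl-1 gene itself was mutant, and the tagged copy was driven either by the promoter of nhx-2, an intestinal sodium/proton exchanger gene, or by its own promoter. The intestinal set held 3 HZL-1 libraries in aak(0), 3 in daf-2 and 1 library of GFP alone labelled aak(0). The endogenous set held 1 HZL-1 library per genotype.

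Ribosomal RNA took between 76.25% and 89.82% of gene reads in the 6 intestinal HZL-1 libraries, 29.96% in the endogenous aak(0) library and 70.35% in the endogenous daf-2 library, although the preparation selected for polyadenylated RNA. The libraries differed strongly in how many genes they detected. In aak(0), 3439, 13967 and 18666 genes had an FPKM above 0 in replicates 1, 2 and 3, against 5135, 11510 and 6076 in daf-2 and 16317 with GFP. Of the 9649 tested genes, 65.9% were listed at 0 in aak(0) replicate 1, 51% in daf-2 replicate 1 and 45.1% in daf-2 replicate 3. In these same libraries a detected coding gene had a median of 186, 174 and 148 reads, against 54 and 31 in aak(0) replicates 2 and 3 and 40 in daf-2 replicate 2. An FPKM of 0 was listed for 8.3%, 11.2% and 11.4% of their genes with over 100 reads, so values are given per library where zeros occur. Across tested genes, aak(0) replicates 2 and 3 correlated at Pearson r = 0.86, and aak(0) replicate 3 with GFP at 0.80, while the other pairs lay between 0.31 and 0.73 (genes are not independent replicates).

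**Figure D1:**
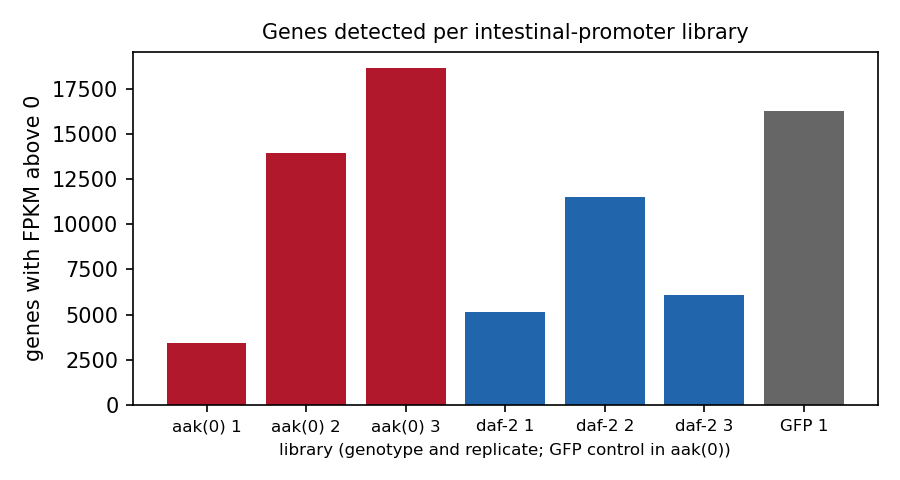
Bars give the number of genes with an FPKM above 0 (vertical axis) in each of the 7 libraries with the intestinal promoter (horizontal axis), coloured by group: aak(0) red, daf-2 blue, GFP grey. The lowest bars are aak(0) replicate 1 with 3439 genes, daf-2 replicate 1 with 5135 and daf-2 replicate 3 with 6076.

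The targeted genes were examined first. Transcripts of hzl-1 (listed as C44H9.4; WBcel235 chromosome V, 12835708 to 12839783) reached 14.2 ± 6.87 FPKM in HZL-1 aak(0) immunoprecipitates and 7.94 ± 5.17 in daf-2 (SD, n = 3 each), against 3.04 with GFP. Transcripts of aak-2 (X, 16796087 to 16803357) were listed at 0, 2.11 and 3.36 FPKM in aak(0) replicates 1 to 3 and at 6.13, 5.31 and 7.90 in daf-2. The GFP library labelled aak(0) held 8.32 FPKM of aak-2, above each daf-2 library, which is unlike what its label says. However, the log2 difference of daf-2 from GFP was -0.34 for aak-2, against a median of -1.28 over all tested genes (0.09 with quantile normalization). Relative to the median gene aak-2 was thus not higher with GFP before such normalization, so its level cannot decide on the label. Transcripts of aak-1 (III, 8756995 to 8761101) were listed at 0, 2.19 and 2.66 FPKM in aak(0), at 0, 2.85 and 6.41 in daf-2 and at 4.43 with GFP. No difference between genotypes in these genes passed the threshold, with limma adjusted p of 0.732 for hzl-1, 0.717 for aak-2 and 0.921 for aak-1. Values over a whole gene can include exons outside a deleted part, so RNA of aak-1 and aak-2 is a weak check of the labels. The nhx-2 gene (II, 7690711 to 7693957) was listed at 9.62, 1.29 and 1.43 FPKM in aak(0) and at 0, 1.28 and 2.74 in daf-2, and daf-2 itself at 14.8 ± 4.25 and 9.72 ± 2.12 (SD, n = 3 each).

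The main comparison asked which transcripts were recovered with intestinal HZL-1 differently in aak(0) and daf-2 dauers. Transcripts of argk-1, which encodes a predicted arginine kinase (WBGene00009706, V, 16103894 to 16105950), rose to 3601, 905 and 2558 FPKM in the 3 aak(0) libraries, against 0.04, 0 and 0 in daf-2. On the log2 scale argk-1 was higher by 10.97 ± 0.62 (SE), higher in 3 of 3 aak(0) libraries than in any daf-2 library, with a limma adjusted p of 0.0113. Transcripts of hmit-1.1, a myo-inositol transporter gene (WBGene00013073, V, 18516789 to 18523875), had the same pattern at 129, 523 and 473 FPKM in aak(0) and 0 in each daf-2 library. Its log2 difference of 8.31 ± 0.69 had a limma adjusted p of 0.0591, above the threshold. With single libraries left out it was 0.00752 without aak(0) replicate 1, 0.959 without aak(0) replicate 2, 0.708 without aak(0) replicate 3, and 0.415, 0.192 and 0.451 without daf-2 replicates 1, 2 and 3. Of the 109 genes at 100 FPKM or more in each aak(0) library, argk-1 and hmit-1.1 were the 2 listed under 1 FPKM in all 3 daf-2 libraries. The 0 FPKM of hmit-1.1 in daf-2 replicate 3 is one of the zeros listed for genes with over 100 reads (141), so its level there may be understated.

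**Figure D2:**
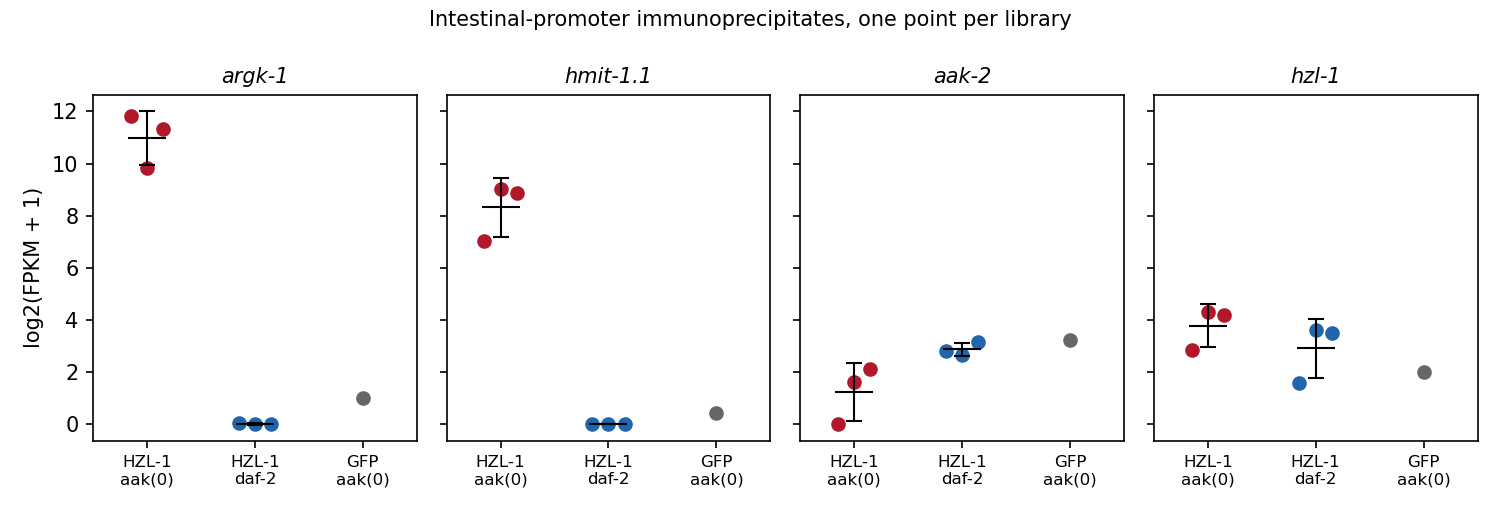
Each point is 1 library with the intestinal promoter, the vertical axis is log2(FPKM + 1), and bars give the mean and SD of the 3 libraries of a genotype. The argk-1 points of HZL-1 in aak(0) (3601, 905 and 2558 FPKM) and the hmit-1.1 points (129, 523 and 473 FPKM) lie above all daf-2 and GFP points, while hzl-1 overlaps between genotypes and the aak-2 point of GFP lies above those of daf-2.

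Reads recovered from the deposited table gave the same picture. For argk-1 there were 77709, 39088 and 114884 reads in aak(0) against 5, 0 and 38 in daf-2, and for hmit-1.1 there were 4840, 40018 and 36848 against 0, 0 and 141. With edgeR's quasi-likelihood test argk-1 (adjusted p = 1.69e-06) and hmit-1.1 (adjusted p = 0.0149) were the 2 genes called, both higher in aak(0). DESeq2 called 5 genes higher in aak(0), without hmit-1.1 (adjusted p = 0.991), namely argk-1 (adjusted p = 0.000196) and 4 genes that had reads in aak(0) replicate 1 alone. The authors' deposited table lists log2 fold changes of daf-2 over aak(0) of -14.25 for argk-1 and -15.01 for hmit-1.1, with an adjusted p of 0.334 for each. Of the 24419 genes with an adjusted p in the authors' deposited table, 0 had one under 0.05 and 3250 had an unadjusted p under 0.05. As described below, the authors' fold changes followed the replicate 1 libraries. Their values are therefore not another test of the same comparison of all HZL-1 libraries.

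In all, limma called 1 of 9649 genes higher in aak(0) and 0 lower, while 420 had an unadjusted p under 0.05 against 482 that chance alone gives. The median over all tested genes was 0.59, and it was 0.18 after median-of-ratios scaling, 0.58 after rescaling to TPM and -0.02 after quantile normalization. Of the 420 genes 395 were higher in aak(0), and the share that was higher fell from 94.0% to 51.8% with quantile normalization. The call of argk-1 ended, at log2 differences between 7.67 and 10.97, with a pseudocount of 10 (adjusted p = 0.118), no filter (0.171) or quantile normalization (0.0938), within a range from 2.26e-49 to 0.326 over all alternatives. It also ended without aak(0) replicate 3 (0.326), daf-2 replicate 1 (0.120), daf-2 replicate 2 (0.163) or daf-2 replicate 3 (0.145), each leaving 0 calls by limma. Without both replicate 1 libraries its adjusted p was 0.0593, and without the 3 libraries with the fewest genes 0.0724. In contrast, leaving out aak(0) replicate 1 gave 545 calls, all higher in aak(0), of which 515 were listed at 0 in both daf-2 replicate 1 and daf-2 replicate 3. Of the 545, 505 were also listed at 0 in the omitted aak(0) replicate 1.

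Mitochondrially encoded genes, which specify subunits of the respiratory chain and the ATP synthase, were recovered more in aak(0): all 12 were higher, with a median of 2.74 on the log2 scale, 2.15 above the median of all genes. That median was 1.71 with quantile normalization, 2.03 with median-of-ratios scaling and 2.78 after rescaling to TPM. The list passed camera (adjusted p = 4.32e-08, and adjusted p = 0.928 with an estimated correlation), and 8 of its 12 members passed when adjusted over the list alone and 0 over all genes tested. Examples were the cytochrome c oxidase genes ctc-1, at 693, 1098 and 1018 FPKM in aak(0) against 172, 267 and 80.7 in daf-2, and ctc-3, at 1140, 2550 and 2115 against 63.8, 737 and 98.9. The cytochrome b gene ctb-1 was at 948, 1399 and 1162 FPKM against 161, 308 and 111, and the ATP synthase gene atp-6 at 189, 327 and 275 against 36.8, 55.3 and 19.4. GFP alone gave 1285 FPKM of ctc-1, 2076 of ctc-3, 1494 of ctb-1 and 160 of atp-6, so these transcripts were also abundant in the control immunoprecipitate. Their mean log2 level was 6.88, 7.71 and 7.60 in aak(0), 4.56, 5.94 and 4.05 in daf-2, and 7.71 with GFP (each on the log2(FPKM + 1) scale). The adjusted p of fry was 0.130. With any 1 library left out camera's adjusted p lay between 2.75e-09 and 0.00414, while the number of passing lists rose from 3 to 8 without aak(0) replicate 1 and to 6 without daf-2 replicate 1.

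Major sperm protein genes, expressed during spermatogenesis, also passed camera as higher in aak(0) (24 of 26 members above the median of all genes, median 1.77, which is 1.18 above it, adjusted p = 0.00296, and adjusted p = 0.968 with an estimated correlation). By limma 0 of the 26 passed when adjusted over the list alone or over all genes. Members such as msp-53 and msp-40 were listed at 0, 28.5 and 15.1 FPKM and at 0, 22.7 and 25.8 in aak(0) replicates 1 to 3, against 40.6, 1.22 and 0 and 22.1, 0.54 and 0 in daf-2. All 26 members were listed at 0 in aak(0) replicate 1, and copies of this family are nearly identical, so the split between members is uncertain. The deposited reads of msp-53, for instance, were 12 in aak(0) replicate 3 and 0 in the other HZL-1 libraries. Neuropeptide genes of the flp and nlp families were lower in aak(0) relative to all genes (50 of 74 members below the median of all genes, median 0.84 below it, adjusted p = 1.94e-04, and adjusted p = 0.928 with an estimated correlation), with 0 members passing by limma when adjusted over the list alone or over all genes. Among them nlp-49 was listed at 0, 21.6 and 18.4 FPKM in aak(0) and at 14.6, 30.1 and 94.2 in daf-2. The most abundant, flp-1, was at 33.7, 16.6 and 16.8 against 0, 35.0 and 117. Its log2 difference of 0.45 was above 0 but below the median of all genes (0.59), and it did not pass. Their call ended without daf-2 replicate 2 (camera adjusted p = 0.106) or daf-2 replicate 3 (0.345), and that of the sperm proteins without aak(0) replicate 2 (0.0521), aak(0) replicate 3 (0.177) or daf-2 replicate 2 (0.0807).

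**Figure D3:**
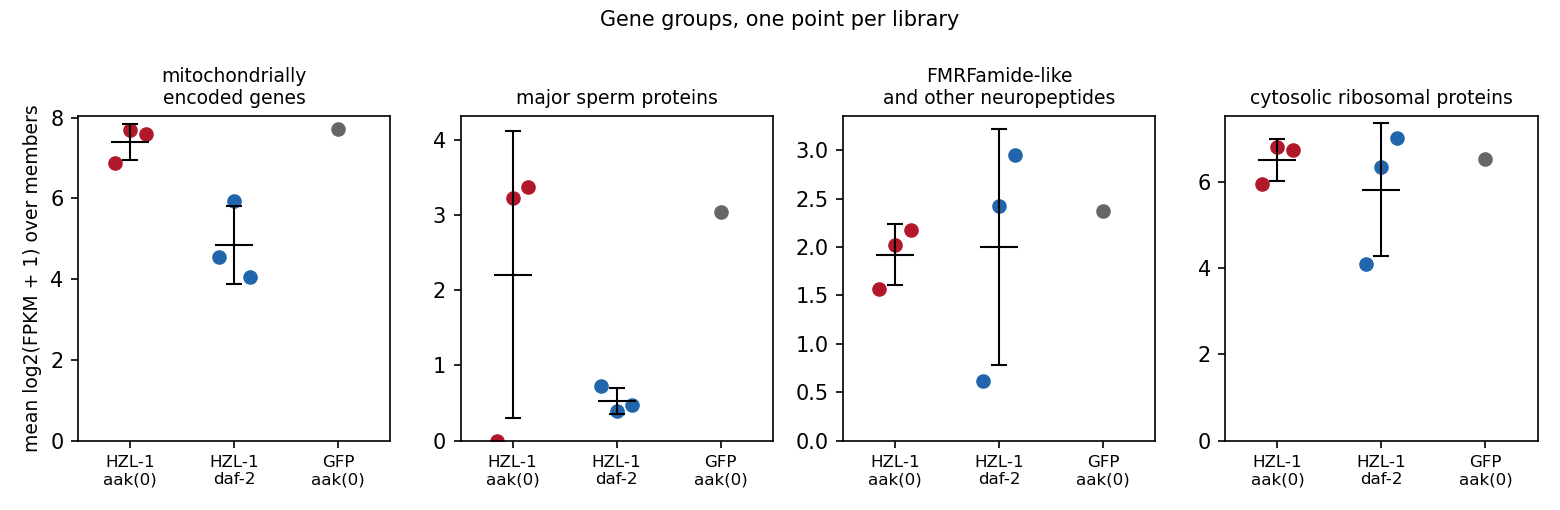
Each point is the mean of log2(FPKM + 1) over the tested members of a gene group in 1 library, with the mean and SD of the 3 libraries per genotype as bars; each panel has its own vertical axis from 0. Mitochondrially encoded genes lie between 6.88 and 7.71 in aak(0) and between 4.05 and 5.94 in daf-2, with GFP at 7.71, whereas the other panels show libraries of both genotypes spread over a wide range.

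The other 26 lists did not pass camera. Yolk protein genes (adjusted p = 0.0543) and insulin-like peptide genes (0.0733) came closest, both lower in aak(0) relative to all genes. The yolk genes vit-2 and vit-6 were listed at 51.3, 0.18 and 0.24 FPKM and at 21.4, 1.37 and 0.46 in aak(0), against 73.4, 0.18 and 0.27 and 123, 0.32 and 0 in daf-2, so both replicate 1 libraries held most of them. Adjusted p was 0.213 for germline markers, 0.271 for histones, 0.338 for pharynx markers and 0.404 for heat shock proteins. It was 0.432 for both fatty acid oxidation and carbohydrate metabolism, 0.580 for neuron markers and for the vacuolar ATPase, 0.592 for body wall muscle markers, 0.656 for the targeted and promoter genes and 0.703 for cytosolic ribosomal proteins. Intestine markers, hypodermis markers, cuticle collagens, the AMPK pathway, triglyceride lipases, fatty acid synthesis, dauer formation genes and autophagy lay between 0.854 and 0.976. The same range held the small RNA pathway, mRNA decay and P bodies, oxidative stress and DAF-16 targets, mitochondrial ribosomal proteins and translation factors. For intestine markers, hypodermis markers, the small RNA pathway, mRNA decay and translation factors camera's direction was up although their medians lay below that of all genes. Of 80 symbol-prefix families 7 passed camera, among them flp, nlp, msp and spe, and 0 with an estimated correlation.

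The comparison with GFP alone asked which transcripts were recovered with HZL-1 above the background of the immunoprecipitation. In aak(0), argk-1 and hmit-1.1 were the 2 genes above GFP, by 9.99 ± 0.88 (limma adjusted p = 0.00379) and 7.88 ± 0.97 (adjusted p = 0.0134) on the log2 scale (SE), each in 3 of 3 libraries. The GFP library held 1 FPKM of argk-1 and 0.35 of hmit-1.1. Its aak-2 level leaves its label aak(0) in doubt without deciding on it, and if the label is wrong this contrast may also hold a difference of genotype. Cytosolic ribosomal protein genes were the 1 list that passed, with 68 of 79 members above the median of all genes, which was -0.79 in this contrast, and a median 0.96 above it (camera adjusted p = 8.85e-08). With an estimated correlation its adjusted p was 0.971, and 0 of its members passed by limma when adjusted over the list alone or over all genes. Its members rps-8 and rpl-6 stood at 541, 442 and 398 FPKM and at 435, 254 and 264, against 330 and 270 with GFP, and under quantile normalization the median of the list lay below that of all genes instead and its call ended (adjusted p = 0.946), while histones passed as lower (adjusted p = 0.0415). Without aak(0) replicate 1, major sperm proteins passed as well (adjusted p = 0.00229). The all-gene median itself was 0.02 with quantile normalization, -0.43 with median-of-ratios scaling and -1.1 after rescaling to TPM.

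Below GFP lay 101 genes, of which 2 were protein-coding and 96 were listed at 0 in all 6 HZL-1 libraries, while 187 of all genes had an unadjusted p under 0.05. Neither gene above GFP passed with a minimum mean of 5 FPKM (limma adjusted p of 0.0502 for argk-1 and 0.226 for hmit-1.1), with quantile normalization (0.187 for both) or without a variance trend (0.208 for both), each of which gave 0 calls. The same held without the 3 libraries with the fewest genes (0.277 and 0.0699). The call of hmit-1.1 also ended with a pseudocount of 10 (0.0622), with genes above 0 in at least 1 HZL-1 library only (0.0508, argk-1 at 0.00198 and 0 genes below GFP), without aak(0) replicate 2 (0.0912) and without aak(0) replicate 3 (0.0742), which raised the count of genes to 158.

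In the daf-2 libraries, 0 genes were above GFP and 103 below it with limma, 728 genes having an unadjusted p under 0.05, 727 of them below GFP. Of the 103 genes, 96 were again the ones listed at 0 in every HZL-1 library and 3 were protein-coding. Relative to a median of -1.28 over all genes (0.09 with quantile normalization, -0.50 with median-of-ratios scaling and -1.55 after rescaling to TPM), mitochondrially encoded genes were lower (12 of 12 below GFP, median -3.07, camera adjusted p = 1.54e-04, with 3 members passing when adjusted over the list alone and 0 over all genes), as were germline markers (adjusted p = 0.0305). With an estimated correlation the adjusted p was 0.892 for both. Among germline markers, the oocyte gene cbd-1 was at 35.8, 3.30 and 0.09 FPKM against 87.1 with GFP, and gld-1 at 14.6, 3.92 and 0.05 against 93.4. Neuropeptides (adjusted p = 7.31e-06), cytosolic ribosomal proteins (0.00107), yolk proteins (0.00562) and insulin-like peptides (0.0305) were higher than other genes. The value with an estimated correlation was again 0.892 for each. If the label aak(0) of the GFP library is right, this contrast also holds a difference of genotype, and if wrong it may not. The count of genes rose to 433 without aak(0) replicate 1 and to 163 without aak(0) replicate 3.

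Of the 6 lists, neuropeptides kept their call with each single library left out and under each scaling. Mitochondrially encoded genes lost it without aak(0) replicate 1 (camera adjusted p = 0.0509) and yolk proteins without daf-2 replicate 1 (0.737). Cytosolic ribosomal proteins lost it without daf-2 replicate 2 (0.105) or daf-2 replicate 3 (0.888). Germline markers lost it without aak(0) replicate 1 (0.0614), aak(0) replicate 2 (0.0552), aak(0) replicate 3 (0.0502), daf-2 replicate 2 (0.273) or daf-2 replicate 3 (0.340). Insulin-like peptides lost it without aak(0) replicate 1 (0.0614), aak(0) replicate 3 (0.0623), daf-2 replicate 2 (0.162) or daf-2 replicate 3 (0.340). Major sperm proteins passed as lower without aak(0) replicate 1 (0.00278), aak(0) replicate 2 (0.0489) or aak(0) replicate 3 (0.0271). Without daf-2 replicate 1 pharynx markers passed as higher (0.0399) and the small RNA pathway as lower (0.0310). With quantile normalization the calls of yolk proteins (0.155), cytosolic ribosomal proteins (0.913) and insulin-like peptides (0.0523) ended, the last also with median-of-ratios scaling (0.115). Major sperm proteins passed as lower with quantile normalization (1.26e-04), median-of-ratios scaling (0.00133) and TPM (0.0346). Pharynx markers (0.0447 and 0.0297) and neuron markers (0.0480 and 0.0239) passed as higher with quantile normalization and median-of-ratios scaling, and body wall muscle markers with the latter (0.0346). The number of passing lists was 3 without daf-2 replicate 2 and 3 without daf-2 replicate 3.

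No gene was above GFP in both genotypes. Below GFP, 101 genes were shared, a count that says nothing about a shared effect: 96 of them were listed at 0 in all 6 HZL-1 libraries and entered through GFP alone, which fixed their call in both contrasts. Independent lists of these sizes would share 1.08, and 20 simulations of unchanged groups that share the control gave 0. Each gene was simulated with its own spread, which is 0 for these 96 genes, so the simulations could not call them. The simulated 0 is therefore no benchmark for the 101 shared genes. Log2 differences from GFP correlated across genes at 0.60 between genotypes with a covariance of 0.80, against 0.75 and 1.94 on average in those simulations. The shared control is a single library that cannot be split.

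With its own promoter, HZL-1 was precipitated from 1 library per genotype, so the difference has no replicate check and compares these libraries only. The library labelled aak(0) held 8965110 reads of argk-1, 37.3% of its gene reads, against 2 in the library labelled daf-2, a ratio of 10840000 (95% interval 3001000 to 89520000). It held 303233 reads of hmit-1.1 against 0, at least 244000-fold higher, and hmit-1.1 ranked 2 among its protein-coding genes. Transcripts of hzl-1 had 11527 reads against 0, at least 9290-fold higher. Transcripts of aak-2, a gene that the label says is missing, had 92248 reads in the library labelled aak(0) and 3937 in that labelled daf-2. This is 56.7-fold higher in CPM (54.9 to 58.5), opposite to what the labels would give. Reads over a whole gene can include exons outside a deleted part, and reads of overlapping genes cannot be separated. The aak-2 level thus leaves the labels in doubt without deciding on them. Transcripts of aak-1 had 638 and 1150 reads, a ratio of 1.34 in CPM (1.22 to 1.48), and nhx-2 had 642 and 825.

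Over 18987 genes with a mean of at least 1 CPM the median difference was 1.92 on the log2 scale. In all 6806 coding genes had reads in the library labelled aak(0) alone, 984 in the library labelled daf-2 alone and 9159 in both. Next after argk-1, hmit-1.1 and hzl-1, the largest differences towards the library labelled aak(0) were in lmd-5, dhc-3, aak-2, oac-51, rnp-1, mgl-3 and 1 gene without a symbol. Apart from aak-2 these had between 1117 and 1466 reads against 0. Towards the library labelled daf-2 they were ttr-16, oma-1, gpa-16, nasp-1, emo-1, fipr-22, pei-2 and 1 gene without a symbol, with between 2606 and 6428 reads against 0, and pqn-51 and another gene without a symbol with 3886 and 4881 against 2 and 16. The oocyte maturation gene oma-1 had 4366 reads there, at least 602-fold higher. Among 6724 genes with a mean of at least 10 CPM, 609 had no read in the library labelled daf-2 and 61 had none in the one labelled aak(0).

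Of the fixed lists 9 of 29 had a median outside the central 95% of random lists matched on expression. Translation factors (median -1.31 on the log2 scale) and cytosolic ribosomal proteins (-1.22) lay below every random list, as did major sperm proteins (-0.23) and neuropeptides (-0.32). The elongation factor gene eef-1A.1 had 1262 CPM in the library labelled aak(0) and 2749 in the library labelled daf-2. Heat shock proteins (-0.96, percentile 0.56) and fatty acid oxidation (-0.17, percentile 1.24) were also low. Cuticle collagens (2.37, percentile 0.42) and mitochondrial ribosomal proteins (0.29, percentile 0.03) were low among matched lists although their medians were above 0. With members under 3 reads set to 3 reads the collagen median was 6.34, and that of the other 7 low lists moved by under 0.1. The targeted and promoter genes were high (0.87, percentile 98.3). Mitochondrially encoded genes had a median of -0.23 (percentile 78.0), with ctc-1 at 2430 CPM in the library labelled aak(0) and 2941 in that labelled daf-2.

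Across 8420 genes present in both sets, the difference between the libraries labelled aak(0) and daf-2 with the endogenous promoter and that between genotypes with the intestinal promoter had a Spearman correlation of -0.09 and a Pearson correlation of -0.08, as a description across genes, which are not independent replicates. The 1 gene called with the intestinal promoter, argk-1, had the same sign, while of 396 genes with an unadjusted p under 0.05 there 148 had the same sign, and 43 after each median was subtracted. These signs rest on the labels of the endogenous pair, which aak-2 leaves in doubt, and turn with them. With a minimum mean of 5 in both tables Spearman's value was 0.012.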

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

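Single libraries were left out as planned, but the use of this as a test of argk-1, and the tests of coding genes alone, of the RNA level in the GFP library, of abundant genes in the endogenous pair and of its transgene were chosen only after the results were seen. For argk-1 the limma contrast of aak(0) and daf-2 was 10.97 on the log2 scale (adjusted p = 0.0113, higher in 3 of 3 aak(0) libraries). The only GFP library is labelled aak(0), and none was made in daf-2. Subtracted from both genotypes it cancels, so a difference between genotypes in the effect of HZL-1 over GFP cannot be estimated. Reads outside annotated genes, which enter no comparison, took 48.57% of all reads in the endogenous-promoter library labelled aak(0) and 4.11% in that labelled daf-2.

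For argk-1 and hmit-1.1 several technical explanations were weighed. Extra copies of the surrounding region are argued against by the 40 flanking tested genes, whose median log2 difference was 0.39 (95% bootstrap interval -0.25 to 0.89). Random loss from the daf-2 libraries remains a candidate cause over genes of all kinds. Of 213 other genes at 100 FPKM or more, 14 (6.57%, exact interval 3.64 to 10.78) lay under 1 FPKM in all 3, above the 5% set beforehand as its mark. However, 0 of the 101 coding genes among the 213 did (upper limit 3.59%), so none of the 14 was coding. This argues against such loss for coding genes, to which argk-1 and hmit-1.1 belong. An effect of 1 library alone is argued against for argk-1 by its values, 905 FPKM or more in each aak(0) library and 0.04 or less in each daf-2 library. Given these values its log2 difference could only stay high with any 1 library left out (10.55 or more), so that test adds no support. Also open is whether aak(0) dauers simply hold more of both RNAs or HZL-1 recovers them, which cannot be told apart. In the GFP library labelled aak(0), argk-1 was at 0.110% of the lowest aak(0) HZL-1 library, but this is 1 library. Its 8.32 FPKM of aak-2, above each daf-2 library though not relative to the median gene, leaves its label in doubt, and a wrong label could give the same value.

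Among the 10 splits of the 6 intestinal HZL-1 libraries into 3 and 3, the real one gave 1 gene and the highest other gave 13, from aak(0) replicate 1 with daf-2 replicates 2 and 3. What gives these 13 genes was not tested. With the real split included, 2 splits gave at least 1 gene. These splits are too few for a share under 0.05.

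The absence of hzl-1 from the endogenous-promoter library labelled daf-2 bears on its label. Random loss was tested on 34 coding genes within 2-fold of the hzl-1 level in the library labelled aak(0): 0% of them had 0 reads, too few genes for an upper limit under 5% (10.3%). Of 230 other coding genes at 100 CPM or more, 1 had no read, hmit-1.1 (upper limit 2.40%), and apart from it and argk-1 with 2 reads all 228 had at least 213 (upper limit of those without a read 1.60%), which argues against random loss of an abundant transcript. Animals without the transgene, a mislabelled library and a difference in recovery of the transcript by its own protein cannot be told apart with 1 library per genotype (0 reads of hzl-1 allow up to 0.0516 CPM). Other values of the pair go both ways. Levels of aak-2, a weak check of the labels, ran opposite to them (92248 reads in the library labelled aak(0) and 3937 in that labelled daf-2). In contrast, argk-1 (8965110 and 2) and hmit-1.1 (303233 and 0) ran as in the intestinal set. If the library labelled daf-2 lacked the transgene, both could be missing for that reason, so these 2 genes cannot decide on the genotype label.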

How the results depend on the processing

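The settings without both replicate 1 libraries, without the 3 libraries with the fewest genes, with genes above 0 in an HZL-1 library, with other scalings for gene lists, with libraries left out for lists against GFP, with an estimated correlation for daf-2 lists against GFP and with the endogenous reads rescaled were chosen after seeing the data. For argk-1, hmit-1.1 and the 3 lists passing between genotypes no alternative changed the direction. Genes called between genotypes numbered 1, and 0 with a pseudocount of 10, no filter, quantile normalization, the replicate block, the authors' deposited table or without the 3 libraries with the fewest genes. They numbered 2 with a mean of at least 5 FPKM, TPM or edgeR, 5 with DESeq2, 36 with robust variances and 27 without both replicate 1 libraries, of which argk-1 was not one and 26 were non-coding. Single libraries left out gave 0 to 545. The authors' fold changes follow the replicate 1 libraries, so their 0 calls are not for the same comparison of 3 libraries with 3. Genes called against GFP numbered 103 in each genotype. No filter gave 2058 in aak(0) and 2348 in daf-2, robust variances gave 6 in each, and genes above 0 in an HZL-1 library gave 1 and 0. A mean of at least 5 FPKM, quantile normalization, no trend, the replicate block and the 3 libraries left out gave 0 in both. Single libraries left out gave 108 to 158 in aak(0) and 106 to 433 in daf-2. The overlap above GFP stayed at 0 in all alternatives run.

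Gene lists passing between genotypes numbered 3, and 0 with an estimated correlation or fry, 6 with a pseudocount of 10, 5 with the replicate block, 10 without both replicate 1 libraries, 9 without the 3 libraries (0 for both with an estimated correlation; the daf-2 arm is then 1 library, assumed to vary like aak(0)) and 2 to 8 with single libraries left out. Against GFP 1 list passed in aak(0) and 6 in daf-2, 0 of either with an estimated correlation, and 1 to 2 and 3 to 7 with single libraries left out. The rank correlation of both sets changed sign, from -0.09 to 0.012, with a minimum mean of 5, no targeted gene passed under 2 other pseudocounts, and the 9 endogenous lists numbered 7 to 10. Over argk-1, hmit-1.1 and the 3 passing lists, 85 alternatives kept direction and side of the threshold, 41 lost the call and 6 gained it. Apart from the shift of scaling given in the report, the cause of these moves was not tested, except that stricter filters test fewer genes. Same-numbered libraries of both genotypes deviated with correlations of -0.11, -0.05 and -0.10, so over all genes the numbers showed no pairing of the libraries. Many tested genes were listed at 0 in some of them, so a shared batch is not excluded. Both replicate 1 libraries held most yolk transcripts. DESeq2 and edgeR were not run against GFP, since that library has FPKM only, and the authors' table holds no such contrast. At the means, spread and depths of these libraries limma recovered 40.3% of the most strongly changed genes of the simulation; depth alone was not varied, so what it limits is not known.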

Other observations

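All tests of this part were chosen only after the results were seen. When both replicate 1 libraries were left out, 10 gene lists passed camera between genotypes, and 0 with an estimated correlation (lowest adjusted p = 0.353). With the preset correlation, neuropeptides (adjusted p = 7.37e-18), cytosolic ribosomal proteins (3.45e-05), pharynx markers (1.81e-04), neuron markers (0.00161), body wall muscle markers (0.00471) and insulin-like peptides (0.00669) were lower in aak(0) relative to other genes. Major sperm proteins (2.48e-05), germline markers (3.88e-04), the small RNA pathway (0.0109) and mitochondrially encoded genes (0.0489) were higher. Germline transcripts were also abundant with GFP: cbd-1 stood at 50.1 and 54.6 FPKM in aak(0) replicates 2 and 3, at 3.30 and 0.09 in daf-2 replicates 2 and 3, and at 87.1 with GFP, while prg-1 stood at 25.2 and 22.1, at 4.18 and 7.39, and at 28.1.

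The deposited log2 fold changes followed the replicate 1 libraries. A regression of the log2 fold changes in the authors' deposited table on the 6 library values gave slopes of -1.12 for aak(0) replicate 1 and 1.16 for daf-2 replicate 1, and the other 4 lay within 0.0024 of 0. A candidate explanation is a model with replicate 1 as a batch of its own and a genotype-by-batch term, whose genotype coefficient is the difference within that batch. Refitting the recovered reads with that design in DESeq2 gave the deposited values over 24419 genes (Pearson r of 1 across genes, median absolute difference 0), whereas a model of genotype alone gave r = 0.365 and one of genotype and replicate number r = 0.370. Under this hypothesis the deposited fold changes rest on the 2 libraries of replicate 1, in which few genes were detected. That batch holds 1 library per genotype and gives no spread. The spread behind the p-values and the 0 calls would then come from the other 4 libraries. No biological explanation was tested.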
